A study of Mus musculus with 11 samples.

How the data were processed

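Total RNA of sorted splenic CD4 T cells was measured on 11 single-channel oligonucleotide arrays of 45101 probe sets, 64 of them controls. The groups were taken from the sample labels: WT naive (3 arrays), MW naive (3), WT IMP (2) and WM IMP (3). Per the labels the mice were female C57BL/6, unmanipulated mice were used at 8 weeks of age and chimeras 8 weeks after transplantation. The sort purity was given as 92% to 99% for all samples.

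The deposited values are log2 values made by the authors with robust multi-array averaging (RMA) and set relative to the mean of the 3 WT naive arrays, which is 0 for every probe set. The base of the logarithm is not stated and was taken from the convention of RMA. The values hold no brightness, so neither the level of a gene nor its distance from background is known, and only differences between arrays were used. The authors also deposited a table of 27800 genes, quantile normalized by its name and relative to the same baseline, which served as an alternative. Over 10943 genes with a single probe set, each array correlated at r of at least 0.954 with its own column of that table and at most 0.883 with the column of another array. Medians of all genes lay within 0.05 of 0 in each array.

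Probe sets assigned to a single gene (38544) were used, and those with several genes (860) or none (5633) and 558 genes with several symbols were left out, which kept 37504 probe sets and 20404 genes. Symbols of 17879 genes were taken from the reference annotation, which changed 2055 of them. A gene's value was the mean of its probe sets. The plan had been the probe set with the highest mean level, which values without brightness do not give. The mean was among the alternatives listed beforehand.

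A linear model with the 4 groups was fitted to all 11 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes). The 6 contrasts were IMP against naive in unmanipulated mice and in chimeras, chimeras against unmanipulated mice in naive and in IMP cells, the average of both contrasts of IMP with naive, and their difference (the interaction). P-values were adjusted by the Benjamini-Hochberg method over all genes within a contrast, and genes at an adjusted p under 0.05 were called. The other tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

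The 31 gene lists were written before the data were examined, as were the tests and most alternatives. They were tested with limma's camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of a contrast. Camera with an estimated correlation and fry, which asks whether a list moves on balance one way and does not compare it with other genes, were alternatives. Lists covered naive and lymphoid homing, activation receptors, memory cytoskeleton, T helper subsets, regulatory, follicular helper, innate-like and cytotoxic T cells, cell cycle, interferon, T cell receptor response and anergy, chemokines and cytokines and their receptors, thymocytes, glycolysis, cholesterol, p53, stress, and markers of other cell types.

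Named genes came from a fixed rule: for each contrast, the 10 called genes with the greatest log2 difference in each direction whose arrays did not overlap, up to 4 called members of each list with the greatest log2 difference, and a fixed set of lineage and sorting genes. For the average and the interaction the overlap of arrays was not a condition. Not all genes named by the rule are printed. Those printed were chosen among them after their values, and partly their calls with arrays left out, had been seen, so counts of printed genes that kept a call are no measure of stability. The plasmacytoid, sex-linked and control genes and Rnpep of the closing section were named outside the rule after their values or pattern had been seen.

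Called genes were tested for clustering on chromosomes with Fisher's exact test (two-sided). Tests on simulated data with 200 changed genes in 10 simulations recovered 54.6% to 67.0% of genes changed by a log2 difference of 1, 93.0% to 96.4% at 2 and 4.90% to 11.6% at 0.5, with 3.91% to 6.17% false calls. A shifted list was called in 10 of 10 simulations of each of 4 contrasts, and an unshifted list in 1 of 10 for WT IMP against WT naive and in 0 for the other contrasts. Genes were drawn independently of each other in these simulations. The real lists had estimated correlations of up to 0.66 (B cell), so the rate for unshifted lists does not carry over to them.

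The alternatives were a block for the replicate number, fits to 2 groups alone, array weights, each probe set by itself, centring of each array, the other deposited table, stricter thresholds and leaving out each array. Alternatives added after the data were seen were robust eBayes, other choices of probe set, a block for the poly-A difference, the 7 arrays without high poly-A controls, the hybridization controls or the 5' minus 3' difference of Gapdh or of actin as a covariate, and leaving out X and Y genes. A filter on dim genes, cyclic loess and an intensity trend in eBayes were planned and not run, because they need brightness.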

Results

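CD4 T cells were sorted from mouse spleen in 4 groups and their total RNA was measured on 11 oligonucleotide arrays, each from a separate biological sample. Naive cells carry little of the surface protein CD44, and innate memory phenotype cells (IMP) carry much of it. WT naive (3 arrays) and WT IMP (2 arrays) came from unmanipulated wild-type mice. MW naive (3 arrays) came from chimeras in which marrow lacking MHC class II, the molecule that presents antigen to CD4 T cells, had been given to irradiated wild-type hosts. WM IMP (3 arrays) came from the opposite chimeras, with wild-type marrow in irradiated hosts lacking MHC class II. By the sort described in the labels, the cells of both kinds of chimera were those of the marrow donor, gated on their CD45 allele. For MW naive the labels disagree on the allele of the hosts, and by 1 of them hosts and donors shared it, so that the gate would not have separated their cells. The values are log2 differences from the mean of the WT naive arrays, so they carry no absolute level, and the number of arrays limits the precision.

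The arrays separated by cell type first. Principal component 1 held 50.7% of the variance, with the 6 naive arrays between -40.27 and -30.25 and the 5 IMP arrays between 31.72 and 51.22. On component 2, which held 17.9%, MW naive lay between -20.75 and -15.63 and WT naive between 10.99 and 15.95, while WM IMP ranged from -49.24 in replicate 1 to 4.62 in replicate 2. The control probe sets for poly-A RNA added during labelling were high in 4 arrays, with values of at least 3.86, against at most -1.80 in the other 7. These 4 arrays comprised 1 array of each group, so the model with the 4 groups had no replicates within them, and no other fit was made there. Each count of genes is given also with this difference as a block and within the other 7 arrays.

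**Figure D1:**
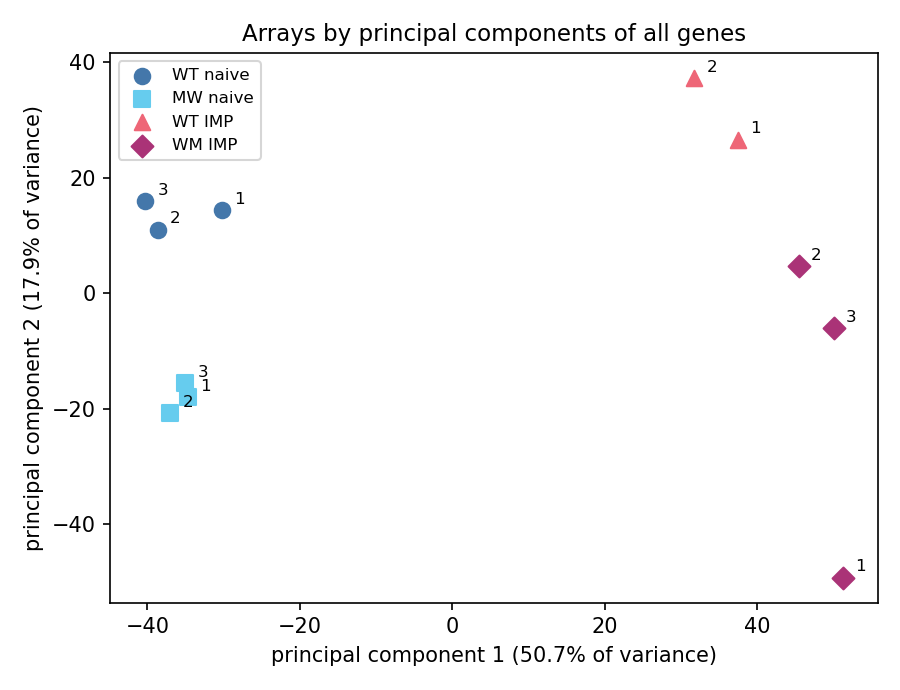
Principal components 1 and 2 of all genes, with 1 point per array, its group as colour and shape and its replicate number beside it. The 5 IMP arrays lie above 31 and the 6 naive arrays below -30 on component 1, and WM IMP replicate 1 lies apart at -49.24 on component 2.

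WT IMP and WT naive cells were compared to ask what distinguishes the memory phenotype from naive cells in unmanipulated mice. In WT IMP cells the genes of T helper 1 identity were among those with the greatest increase. Tbx21, which encodes the T helper 1 transcription factor T-bet, was 65.6-fold higher (log2 difference 6.03 ± 0.32 SE, adjusted p = 1.76e-06), and the chemokine receptors Cxcr3 (6.69 ± 0.31) and Cxcr6 (6.46 ± 0.29) rose with it. The effector cytokines Il4 (42.3-fold, 5.40 ± 0.20, adjusted p = 1.32e-07) and Ifng (25.7-fold, 4.68 ± 0.27, adjusted p = 2.71e-06) were both higher in WT IMP. RNA of a sorted population does not show whether single cells made both. Genes of naive cells fell. Igfbp4, which encodes a binding protein of growth factors, was at -4.48 ± 0.15, Dapl1 at -3.27 ± 0.19 and Lef1, a transcription factor of naive and immature T cells, at -3.12 ± 0.35. All values in this comparison are for 2 WT IMP against 3 WT naive arrays, and ± gives the standard error from limma.

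Of 20404 genes tested, 1563 changed at an adjusted p under 0.05, of which 1084 were higher and 479 lower in WT IMP, and 937 changed at least 2-fold. Cd44, which encodes a surface protein used in the sort, served as a check and was 2.01 ± 0.17 higher. The pan-T-cell gene Cd3e (-0.02 ± 0.13) and Cd4 (-1.0 ± 0.37, adjusted p = 0.162) did not pass the test. The calcium-binding proteins S100a4 (5.79 ± 0.35) and S100a6 (5.38 ± 0.31) rose as well. Among other lower genes were Ampd1 (-3.92 ± 0.29), an enzyme of purine nucleotide metabolism, and Pdlim4 (-3.49 ± 0.43).

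The list of naive and lymphoid homing genes fell in 15 of its 20 measured members and rose in none (adjusted p = 9.61e-26), including Ccr7 (-2.10 ± 0.28), the receptor that guides cells into lymph nodes. Adjusted over the list alone, 20 fell. The activation and costimulation receptors rose in 15 of 20 members (18 adjusted over the list alone, adjusted p = 1.65e-23), among them Klrg1 (4.44 ± 0.27), Lag3 (3.96 ± 0.40), Havcr2 (3.48 ± 0.37) and Ctla4 (3.20 ± 0.21). The memory cytoskeleton and calcium binding list rose in 12 of 20 (12 adjusted over the list alone, adjusted p = 4.04e-14), with Myo1f at 4.65 ± 0.26 and Lgals3 at 3.16 ± 0.33. The innate-like T and NKT list rose in 16 of 21 (20 adjusted over the list alone, adjusted p = 1.29e-28), with Nkg7 (4.81 ± 0.34), the adaptor Tyrobp (4.68 ± 0.29) and the chemokine Xcl1 (4.45 ± 0.31). Zbtb16, which encodes PLZF, the transcription factor of innate-like T cells, was 5.98-fold higher (2.58 ± 0.18).

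Genes of several T helper programmes rose in this comparison of sorted populations. The Th1 list rose in 8 of 17 members (13 adjusted over the list alone, adjusted p = 1.18e-15), including the chemokine Ccl5 (4.93 ± 0.37). The Th2 list rose in 7 of 17 and fell in 1 (8 and 1 adjusted over the list alone, adjusted p = 3.86e-05), with the interleukin 33 receptor Il1rl1 at 1.77 ± 0.22 and the transcription factor Gata3 at 0.70 ± 0.12. The Th17 list rose in 6 of 13 (8 adjusted over the list alone, adjusted p = 9.61e-09), with Tmem176b (3.85 ± 0.25) and Rora (1.97 ± 0.16), while Il17a itself was at -0.04 ± 0.19. The regulatory T cell list rose in 16 of 19 (17 rose and 1 fell adjusted over the list alone, adjusted p = 4.90e-21), with Foxp3, its defining transcription factor, 3.65-fold higher (1.87 ± 0.20), Ebi3 at 3.44 ± 0.32 and Nrp1 at 2.86 ± 0.26. The T follicular helper list rose in 10 of 19 (10 adjusted over the list alone, adjusted p = 1.34e-10), with Maf at 3.64 ± 0.14 and Cxcr5 at 2.38 ± 0.39, while Bcl6, the transcription factor of that programme, was at 0.22 ± 0.19 (adjusted p = 0.736).

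The cytotoxic effector list rose in 7 of 14 and fell in 1 (9 and 2 adjusted over the list alone, adjusted p = 1.78e-06), with Slamf7 at 3.22 ± 0.31 and granzyme B, Gzmb, at 2.98 ± 0.46. The chemokine receptors rose in 8 of 17 and fell in 1 (10 and 1 adjusted over the list alone, adjusted p = 7.75e-10), with Ccr2 at 3.06 ± 0.22. The cytokines rose in 11 of 25 (12 rose and 1 fell adjusted over the list alone, adjusted p = 1.17e-07). The cell cycle list rose in 12 of 34 and fell in 1 (19 and 1 adjusted over the list alone, adjusted p = 2.78e-11), with the proliferation marker Mki67 11.2-fold higher (3.49 ± 0.33) and Ccnb2 at 2.63 ± 0.25. The TCR immediate early list rose in 6 of 26 and fell in 1 (10 and 2 adjusted over the list alone, adjusted p = 0.000621), led by the transcription factor Bhlhe40 (4.37 ± 0.21). Its call was lost at adjusted p = 0.0800 with an estimated correlation. The same held for the cytokine receptors (11 rose and 4 fell of 26, 12 and 8 adjusted over the list alone, adjusted p = 0.0168; adjusted p = 0.107 with an estimated correlation), where Il12rb1 was at 3.77 ± 0.28 and Il18rap at 3.01 ± 0.22. It also held for the anergy and TCR attenuation list (8 rose and 2 fell of 21, 9 and 3 adjusted over the list alone, adjusted p = 0.0206; adjusted p = 0.160 with an estimated correlation). The interferon response lost its call as well (6 rose and 1 fell of 28, 8 and 3 adjusted over the list alone, adjusted p = 0.0206; adjusted p = 0.446 with an estimated correlation), with Gbp3 at 1.98 ± 0.26 and Oas1a at 1.73 ± 0.26.

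Markers of other cell types also rose in WT IMP. The dendritic cell list rose in 9 of 11 members (10 adjusted over the list alone, adjusted p = 1.20e-14), with Siglech, a surface receptor of plasmacytoid dendritic cells, at 5.48 ± 0.61, Itgax at 4.31 ± 0.25 and the growth factor receptor Flt3 at 3.92 ± 0.24. The MHC class II presentation list rose in 7 of 8 (7 adjusted over the list alone, adjusted p = 3.56e-10), with H2-Aa at 3.01 ± 0.43 and H2-Ab1 at 3.0 ± 0.32. The monocyte, macrophage and granulocyte list rose in 9 of 22 (12 adjusted over the list alone, adjusted p = 3.12e-09), with Mpeg1 at 4.92 ± 0.47 and Cd68 at 3.81 ± 0.34. The plasma cell list rose in 3 of 8 (3 adjusted over the list alone, adjusted p = 0.000541), with Xbp1 at 1.28 ± 0.24. The B cell list rose in 4 of 17 (4 adjusted over the list alone, adjusted p = 0.0221), with Ly86 at 3.21 ± 0.28, and had adjusted p = 0.586 with an estimated correlation. The NK cell list rose in 3 of 9 (3 rose and 1 fell adjusted over the list alone, adjusted p = 0.0144; adjusted p = 0.12 with an estimated correlation), with Klrb1c at 3.32 ± 0.41. The CD8 T cell list did not pass (1 rose and 1 fell of 5, 2 and 1 adjusted over the list alone, adjusted p = 0.309), and Cd8a was at 0.61 ± 0.30. Neither the erythroid list (0 of 11, 0 adjusted over the list alone, adjusted p = 0.370) nor the platelet and megakaryocyte list (0 of 8, 0 adjusted over the list alone, adjusted p = 0.833) had a member that passed in limma.

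Metabolic and stress lists were tested too. The glycolysis list rose in 3 of 15 (3 adjusted over the list alone, adjusted p = 0.0221; adjusted p = 0.0925 with an estimated correlation), with the enzyme gene Tpi1 at 1.05 ± 0.20. The thymocyte and recent thymic emigrant list did not pass (2 rose and 4 fell of 19, 2 and 4 adjusted over the list alone, adjusted p = 0.890), with Ccr9 at 1.86 ± 0.13, and its median was 0.02 although the test pointed lower. The p53 target list (1 rose of 20, 1 adjusted over the list alone, adjusted p = 0.890), with Pmaip1 at 3.65 ± 0.26, and the heat shock and stress list (4 rose and 1 fell of 17, 5 and 3 adjusted over the list alone, adjusted p = 0.705), with Gadd45b at 1.43 ± 0.21, did not pass, and their medians of -0.03 and -0.18 had the opposite sign to the test. The cholesterol synthesis list had no called member of 18 (0 adjusted over the list alone, adjusted p = 0.254).

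With limma's camera, 24 of the 31 lists passed in this comparison, 17 of them also with an estimated correlation, and 23 passed with fry. The count of changed genes was 1504 with the poly-A difference as a block and 478 in the 7 arrays without high poly-A controls, where WT IMP kept a single array. It was 702 without WT IMP 1, 969 without WT IMP 2 and 982 without WT naive 3. With the Gapdh 5' minus 3' difference, a sign of RNA integrity, as a covariate it was 1020. That difference was -4.23 in WT IMP 1 and -0.27 in WT IMP 2. Of the called genes named here, Xbp1 and Tpi1 lost their call without WT IMP 1. In the 7 arrays Gadd45b, Gata3, Tpi1 and Xbp1 lost theirs.

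WM IMP and MW naive cells were compared to ask whether cells enriched for each phenotype in the chimeras differ in the same way. The same T helper 1 and effector genes were prominent: Tbx21 was 70.7-fold higher in WM IMP (6.14 ± 0.29, adjusted p = 1.72e-07), Il4 76.4-fold (6.26 ± 0.18, adjusted p = 7.66e-09) and Ifng 11.8-fold (3.56 ± 0.24, adjusted p = 2.37e-06). S100a4 (7.33 ± 0.32), Cxcr3 (6.44 ± 0.27), Ccl5 (6.18 ± 0.33) and Nkg7 (5.92 ± 0.30) rose as well. The MHC class II genes H2-Aa (6.72 ± 0.38), H2-Eb1 (6.59 ± 0.37) and H2-Ab1 (6.22 ± 0.29) were also among the 10 named genes with the greatest increase. In this comparison the marrow of MW naive, not that of WM IMP, lacked MHC class II. Among the lower genes were Dapl1 (-4.07 ± 0.17), Pdlim4 (-4.68 ± 0.38), Ccr7 (-3.32 ± 0.25) and Xist (-6.37 ± 0.23), the RNA that silences 1 X chromosome in female cells. Each value is for 3 against 3 arrays.

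In all, 2667 genes changed, 1318 higher and 1349 lower in WM IMP, and 1151 changed at least 2-fold. Cd44 was 1.85 ± 0.16 higher, while Cd3e (0.19 ± 0.11) and Cd4 (0.37 ± 0.33) did not pass. The survival receptor Il7r was at -1.22 ± 0.21 (adjusted p = 0.00230). The naive and lymphoid homing list fell in 15 of 20 members and rose in none (16 fell adjusted over the list alone, adjusted p = 2.16e-17), with Lef1 at -3.09 ± 0.31. The activation and costimulation receptors rose in 17 of 20 (17 adjusted over the list alone, adjusted p = 1.16e-21), with the integrin Itgae at 4.47 ± 0.26 and Cd83 at 4.36 ± 0.25. The innate-like T and NKT list rose in 17 of 21 (18 adjusted over the list alone, adjusted p = 1.16e-21), with Tyrobp at 5.41 ± 0.26 and Zbtb16 at 2.55 ± 0.16. The Th1 list rose in 11 of 17 (13 adjusted over the list alone, adjusted p = 3.48e-15). The Th17 list rose in 9 of 13 (9 adjusted over the list alone, adjusted p = 6.23e-11) with Tmem176a at 4.04 ± 0.27 but Il17a at 0.37 ± 0.17. All 19 members of the regulatory T cell list changed, 17 higher and 2 lower (17 and 2 adjusted over the list alone, adjusted p = 2.44e-19), with Foxp3 10.4-fold higher (3.37 ± 0.18). The T follicular helper list rose in 12 of 19 (14 adjusted over the list alone, adjusted p = 1.07e-13), with Maf at 4.27 ± 0.13, Cxcr5 at 3.26 ± 0.35 and Bcl6 at 0.81 ± 0.17.

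The TCR immediate early list rose in 12 of 26 and fell in 3 (14 and 4 adjusted over the list alone, adjusted p = 7.78e-05), with Bhlhe40 at 4.82 ± 0.19 and Egr2 at 2.10 ± 0.15. The cell cycle list rose in 11 of 34 and fell in 2 (13 and 4 adjusted over the list alone, adjusted p = 0.000747; adjusted p = 0.136 with an estimated correlation), with Mki67 at 3.81 ± 0.29. The cholesterol synthesis list fell in 5 of 18 (7 adjusted over the list alone, adjusted p = 6.32e-06), with the squalene epoxidase Sqle at -1.99 ± 0.39, and had adjusted p = 0.171 with an estimated correlation. The interferon response did not pass (7 rose and 4 fell of 28, 10 and 6 adjusted over the list alone, adjusted p = 0.203), with Mx1 at 2.51 ± 0.52 and Ifit2 at -1.56 ± 0.12. Among markers of other cell types, the dendritic cell list rose in 7 of 11 (9 adjusted over the list alone, adjusted p = 1.28e-10), with Itgax at 4.71 ± 0.23 and Siglech at 3.61 ± 0.55. The MHC class II presentation list rose in 7 of 8 (7 adjusted over the list alone, adjusted p = 6.95e-13). The B cell list rose in 10 of 17 (13 adjusted over the list alone, adjusted p = 7.59e-10; adjusted p = 0.12 with an estimated correlation), with Ly86 at 3.64 ± 0.25 and Ms4a1, which encodes CD20, at 2.22 ± 0.44. The CD8 T cell list rose in 2 of 5 (2 adjusted over the list alone, adjusted p = 0.00550), with Cd8a at 1.81 ± 0.27. The monocyte, macrophage and granulocyte list rose in 7 of 22 (8 adjusted over the list alone, adjusted p = 5.70e-08), with Mpeg1 at 4.49 ± 0.42 and Cd68 at 3.85 ± 0.31, and the plasma cell list in 2 of 8 (4 adjusted over the list alone, adjusted p = 0.00112), with Jchain at 3.43 ± 0.51. The NK cell list rose in 5 of 9 (6 rose and 1 fell adjusted over the list alone, adjusted p = 0.00112; adjusted p = 0.0553 with an estimated correlation), with Klrb1c at 2.61 ± 0.37.

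With camera, 24 of 31 lists passed, 18 of them with an estimated correlation, and 25 passed with fry. The count of 2667 was 2698 with the poly-A difference as a block and 1160 in the 7 arrays without high poly-A controls. It was 1530 when only these 6 arrays were fitted and 1667 with the hybridization control level, whose mean was 2.71 in WM IMP and 1.37 in MW naive, as a covariate. Of the called genes 49.4% were higher here and 68.3% with that covariate. Sqle and Ms4a1 lost their call with that covariate, and Sqle, Mx1, Il7r and Bcl6 lost it in the 7 arrays.

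Both comparisons of IMP with naive cells called many of the same genes. The 1563 and 2667 called genes shared 1104 with the same sign, 813 higher and 291 lower, against 70.0 and 31.7 for independent lists, and 0 with opposite signs, against 102.6. These counts come from limma, and the comparisons share no array. Across the 20404 genes, which are not independent replicates, the log2 differences had Pearson's r = 0.777 and Spearman's rho = 0.515. Averaged over both kinds of mice, 3583 genes changed (1836 higher and 1747 lower in IMP), with Cxcr3 at 6.57 ± 0.21, S100a4 at 6.56 ± 0.24, Cxcr6 at 6.11 ± 0.19, Tbx21 at 6.09 ± 0.22 and Il4 at 5.83 ± 0.13. The averaged decrease was greatest for Pdlim4 (-4.08 ± 0.29), Igfbp4 (-3.68 ± 0.10) and Dapl1 (-3.67 ± 0.13). With camera, 24 of 31 lists passed in the average, and 18 also passed with an estimated correlation.

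The shared count was 1093 with the poly-A difference as a block and 377 in the 7 arrays without high poly-A controls, and the averaged count was 3567 and 1539. The shared count was 604 without WT IMP 1 and 735 without WT IMP 2, and the averaged count was 2309 without WT IMP 1.

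**Figure D2:**
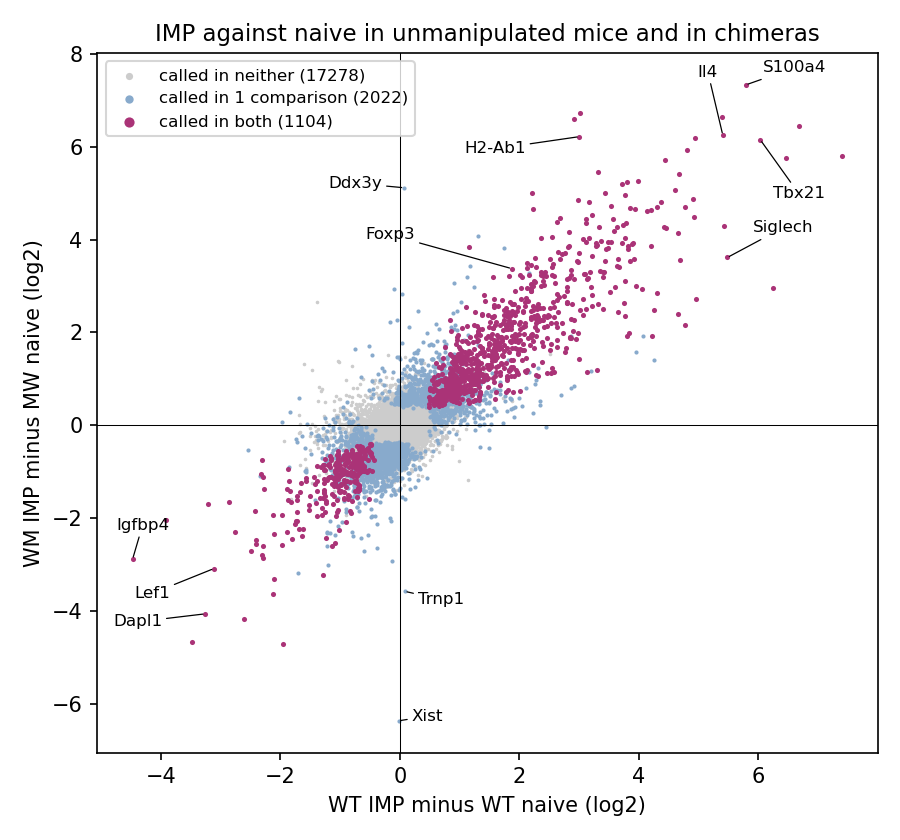
Log2 differences of IMP from naive cells, with unmanipulated mice on the x axis (2 against 3 arrays) and chimeras on the y axis (3 against 3 arrays), and 1 point per gene, coloured by the number of comparisons that called it. Tbx21, Il4 and S100a4 are high on both axes, while Xist and Ddx3y lie near 0 on the x axis and apart on the y axis.

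The interaction asked whether the difference between IMP and naive cells was itself different in the chimeras. It was the log2 difference in the chimeras minus that in unmanipulated mice and passed for 12 genes, 9 with a positive and 3 with a negative value, and 1531 genes had an unadjusted p under 0.05. The genes tied to sex chromosomes stood out: Xist was at -6.35 ± 0.34 (adjusted p = 8.78e-06), and the Y-linked genes Ddx3y (5.05 ± 0.19), Eif2s3y (3.03 ± 0.23) and Kdm5d (1.74 ± 0.18) were positive. Trnp1, a nuclear protein gene, was at -3.67 ± 0.21, H2-Ab1 at 3.22 ± 0.43, the protease gene Ctse at 2.80 ± 0.39 and the antiviral gene Ifitm3 at 2.79 ± 0.39. The remaining genes were G530011O06Rik (2.68 ± 0.34), Ppfia4 (-2.47 ± 0.27), Igfbp4 (1.59 ± 0.20) and Gprc5b (1.55 ± 0.22). Tbx21 (0.11 ± 0.43), Il4 (0.85 ± 0.26), Zbtb16 (-0.03 ± 0.24) and Foxp3 (1.51 ± 0.26, adjusted p = 0.0817) did not pass.

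Of the lists, 11 passed the interaction with camera, 0 passed with an estimated correlation and 0 with fry. The MHC class II presentation list had the lowest p (4 of 8 members positive and 0 negative adjusted over the list alone, adjusted p = 6.75e-08; adjusted p = 0.105 with an estimated correlation). Its median was -0.54 in MW naive, whose marrow lacks MHC class II, against WT naive. In WM IMP against WT IMP the median was 0.38 and no member was called. The count of 12 genes was 18 with the poly-A difference as a block and 1 in the 7 arrays without high poly-A controls, and it ranged from 4 without WT IMP 1 to 63 without WM IMP 2. Xist, Ddx3y, Eif2s3y and Trnp1 kept their call whichever array was left out. It was 4 with the Gapdh covariate and 24, of which 62.5% positive against 75%, in the other deposited table. Without WM IMP 2, 34.9% of the 63 were positive.

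MW naive and WT naive cells were compared to ask how naive cells of the chimeras differ from those of unmanipulated mice. The MHC class II genes H2-Eb1 (-3.28 ± 0.37), H2-Aa (-3.08 ± 0.38) and H2-Ab1 (-3.07 ± 0.29, adjusted p = 0.00133) were lower in MW naive, whose marrow lacks MHC class II, and served as a check of that label. Genes that T cell receptor signals induce within minutes to hours were lower too: Egr1 was at -1.68 ± 0.16, Nr4a1, which encodes Nur77, at -1.39 ± 0.17, Jun at -1.32 ± 0.17 and Egr2 at -1.14 ± 0.15. The highest log2 differences were those of Trnp1 (14.5-fold, 3.85 ± 0.14, adjusted p = 3.33e-07) and Drc1 (3.14 ± 0.36). The chemokine receptor Cxcr4 (1.99 ± 0.33) and the survival receptor Il7r (0.95 ± 0.21) rose, while Foxp3 was at -0.82 ± 0.18 (adjusted p = 0.0363) and Cd5, an inhibitor of receptor signalling, at -1.06 ± 0.23. Each value is for 3 against 3 arrays.

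In all, 556 genes changed, 144 higher and 412 lower in MW naive, and 231 changed at least 2-fold. Other lower genes were Art2b (-2.78 ± 0.33), an ectoenzyme of T cells, Ifitm3 (-2.21 ± 0.26), H2-T24 (-2.17 ± 0.26), Nkg7 (-1.84 ± 0.30), Igfbp4 (-1.27 ± 0.14) and the cytokine receptor Il21r (-1.15 ± 0.16), and other higher genes were Coro2a (2.12 ± 0.24) and Pde1b (1.61 ± 0.16). Cd44 (-0.31 ± 0.16), Cd3e (-0.29 ± 0.11), Il4 (0.03 ± 0.18), Ifng (-0.04 ± 0.24) and Zbtb16 (-0.13 ± 0.16) did not pass.

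With camera, 21 of 31 lists passed, all lower in MW naive, 0 passed with an estimated correlation and 12 with fry. The TCR immediate early list fell in 8 of 26 members and rose in none (11 fell and 1 rose adjusted over the list alone, adjusted p = 2.12e-08; adjusted p = 0.0564 with an estimated correlation), and its median was -0.55. The interferon response fell in 4 of 28 (12 fell and 1 rose adjusted over the list alone, adjusted p = 2.41e-06; adjusted p = 0.131 with an estimated correlation), with Zbp1 at -1.09 ± 0.24 and Oas1a at -1.06 ± 0.23. The regulatory T cell list fell in 5 of 19 (6 adjusted over the list alone, adjusted p = 0.000186; adjusted p = 0.107 with an estimated correlation). The cytotoxic effector list fell in 3 of 14 (3 adjusted over the list alone, adjusted p = 0.000186; adjusted p = 0.0564 with an estimated correlation), with Ctsw at -0.91 ± 0.13. The naive and lymphoid homing list fell in 2 of 20 and rose in 1 (9 and 1 adjusted over the list alone, adjusted p = 4.22e-05; adjusted p = 0.0564 with an estimated correlation). Among other cell types, the monocyte, macrophage and granulocyte list fell in 2 of 22 (10 adjusted over the list alone, adjusted p = 7.37e-06; adjusted p = 0.131 with an estimated correlation), with lysozyme, Lyz2, at -1.92 ± 0.23 and Fcgr3 at -1.35 ± 0.24. The NK cell list fell in 1 of 9 (2 adjusted over the list alone, adjusted p = 0.00389; adjusted p = 0.131 with an estimated correlation). The CD8 T cell list (0 of 5 called, 1 fell adjusted over the list alone, adjusted p = 0.0347; adjusted p = 0.131 with an estimated correlation) and the B cell list (0 of 17, 0 adjusted over the list alone, adjusted p = 0.0483; adjusted p = 0.691 with an estimated correlation) were lower as well.

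Signs of RNA integrity moved with this comparison. The Gapdh 5' minus 3' difference was -3.03 ± 1.48 (SD, n = 3) in MW naive and 0 ± 0.42 (SD, n = 3) in WT naive, and with it as a covariate 14 of the 556 genes kept their call, among them Trnp1, Coro2a, Pde1b, H2-Ab1, Ifitm3 and Egr1. The median of the TCR immediate early list was then -0.34, against -0.55 without a covariate. The same difference for actin was -1.0 ± 0.29 (SD, n = 3) in MW naive and 0 ± 0.31 (SD, n = 3) in WT naive, and with it as a covariate 80 of the 556 kept their call. The median of that list was -0.42 with the actin covariate, -0.56 with the hybridization covariate and -0.62 in the 7 arrays without high poly-A controls. Within WT IMP, replicate 1 minus replicate 2, which differ in the same Gapdh measure, correlated at r = 0.543 with this comparison across the 556 called genes, which are not independent replicates. These 2 arrays also differ in the poly-A controls (4.26 against -1.97), which were high in 1 of 3 arrays of each naive group. The count was 543 with the poly-A difference as a block, 15 in the 7 arrays without high poly-A controls, and 153, 189, 132, 148 and 123 without WT naive 1, 2 and 3 and MW naive 1 and 2 in turn. It was 1017 without WM IMP 1, which changes only the estimate of spread. In the 7 arrays the median absolute difference of the 556 genes was 0.96, against 0.89 in all arrays. Their signs could not change there, because the arrays of MW naive and WT naive did not overlap for any of the 556. Cd5, Cxcr4, Fcgr3, Foxp3, Il7r, Nkg7, Oas1a and Zbp1 each lost their call when at least 1 array was left out. Of the called genes named here Trnp1, Drc1, H2-Ab1 and H2-T24 kept theirs in the 7 arrays. Of the called genes, 25.9% were higher here, 41.7% in the other deposited table and 44.8% with the hybridization covariate, where 216 of the 556 kept their call and 525 were called. With the probe set of the highest relative mean, a choice that favours values above the baseline, 164 were higher and 173 lower.

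WM IMP and WT IMP cells were compared to ask how memory phenotype cells of the chimeras differ from those of unmanipulated mice. Genes of the sex chromosomes were among those that differed most: Xist was 68.3-fold lower in WM IMP (-6.09 ± 0.25, adjusted p = 5.59e-07), while the Y-linked Ddx3y (5.12 ± 0.14, adjusted p = 1.28e-08), Eif2s3y (3.04 ± 0.17) and Kdm5d (1.88 ± 0.13) were higher, although the labels give female donors and hosts. The protease gene Ctse was 3.67 ± 0.29 higher and the synaptic scaffold gene Ppfia4 was at -2.34 ± 0.20. Both lie among the 200 tested genes around Ptprc, which encodes CD45, where donor DNA could explain some calls. The immediate early genes Btg2 (-2.06 ± 0.33), Jun (-1.70 ± 0.19), Fos (-1.46 ± 0.28) and Egr1 (-1.10 ± 0.17) were lower, as was the homing receptor gene Ccr7 (-1.40 ± 0.28). The NK receptor gene Klrk1, which encodes NKG2D, was at -2.50 ± 0.43, and the integrin Itgae at 1.45 ± 0.29. Each value is for 3 against 2 arrays.

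In all, 259 genes changed, 76 higher and 183 lower in WM IMP, and 160 changed at least 2-fold. Several genes of IMP cells did not pass here: Tbx21 was at -1.0 ± 0.32 (adjusted p = 0.147), Ifng at -1.16 ± 0.27 (adjusted p = 0.0638), Il4 at 0.88 ± 0.20 (adjusted p = 0.0543), Zbtb16 at -0.17 ± 0.18 and Foxp3 at 0.69 ± 0.20. Other genes that passed were Stk25 (-2.95 ± 0.40), Prg4 (-2.26 ± 0.28), Cxcr6 (-1.60 ± 0.29), Klrc1 (-0.95 ± 0.19), the leukotriene receptor Ltb4r1 (1.68 ± 0.31) and Ikzf2 (0.85 ± 0.17), a transcription factor of regulatory T cells.

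With camera, 11 of 31 lists passed, 9 lower and 2 higher, 0 passed with an estimated correlation and 9 with fry. The cell cycle list fell in 1 of 34 members (16 adjusted over the list alone, adjusted p = 5.32e-08; adjusted p = 0.257 with an estimated correlation), with Birc5 at -2.00 ± 0.31. The interferon response had no called member (12 fell adjusted over the list alone, adjusted p = 5.32e-08; adjusted p = 0.257 with an estimated correlation). The TCR immediate early list fell in 5 of 26 (11 fell and 1 rose adjusted over the list alone, adjusted p = 0.000444; adjusted p = 0.257 with an estimated correlation). The naive and lymphoid homing list fell in 4 of 20 (6 adjusted over the list alone, adjusted p = 0.00145; adjusted p = 0.257 with an estimated correlation), with Dapl1 at -1.29 ± 0.19. The heat shock and stress list fell in 2 of 17 and rose in 1 (8 and 2 adjusted over the list alone, adjusted p = 0.00884; adjusted p = 0.257 with an estimated correlation), with Hmox1 at -1.09 ± 0.14, Hspa1a at -0.87 ± 0.15 and Gadd45b at 1.17 ± 0.21. The monocyte, macrophage and granulocyte list fell in 3 of 22 (7 adjusted over the list alone, adjusted p = 0.00145; adjusted p = 0.306 with an estimated correlation), with C1qb at -1.59 ± 0.32 and Cd5l at -1.48 ± 0.26. The cholesterol synthesis list had no called member (1 of 18 fell adjusted over the list alone, adjusted p = 0.000309; adjusted p = 0.407 with an estimated correlation). The innate-like T and NKT list fell in 3 of 21 (4 adjusted over the list alone, adjusted p = 0.00691; adjusted p = 0.263 with an estimated correlation). The Th1 list was lower, with 1 of 17 called higher and 1 lower (1 and 5 adjusted over the list alone, adjusted p = 0.0314; adjusted p = 0.447 with an estimated correlation). The higher lists were Th17 (1 of 13 called, 1 adjusted over the list alone, adjusted p = 0.00691; adjusted p = 0.257 with an estimated correlation) and B cell (0 of 17 called, 2 adjusted over the list alone, adjusted p = 0.00145; adjusted p = 0.497 with an estimated correlation).

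The count of 259 was 196 with the poly-A difference as a block, 9 in the 7 arrays without high poly-A controls, 8 when only these 5 arrays were fitted and 7 with the hybridization control level as a covariate. In the 7 arrays, where WT IMP kept a single array, the median absolute difference of the 259 genes was 1.23, against 1.10 in all arrays. Of the called genes, 29.3% were higher here and 39.9% in the other deposited table. With the probe set of the highest relative mean 193 were higher and 187 lower, in the 5 arrays 6 were higher and 2 lower, and with the hybridization covariate 5 and 2. With the Gapdh covariate the count was 212, and 166 of the 259 kept their call. With the actin covariate it was 131, and 72 kept it. The count was 48 without WT IMP 1, 14 without WT IMP 2 and 929 without WM IMP 2. It was 105, 153 and 95 without WT naive 1, 2 and 3 and 141 and 146 without MW naive 1 and 2, which change only the estimate of spread. Of the 26 called genes named here, 7 kept their call whichever array was left out, namely Xist, Ddx3y, Eif2s3y, Kdm5d, Ctse, Ppfia4 and Jun. Xist, Ddx3y, Eif2s3y and Kdm5d are sex-linked, and Ctse and Ppfia4 lie near Ptprc. Of the 7 genes, Kdm5d, Ppfia4 and Jun lost their call in the 7 arrays, Ppfia4 and Jun with the hybridization covariate and Jun in the 5 arrays fitted alone. In each of these 3 settings 20 of the 26 lost their call, and with the Gapdh covariate 3 did.

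Both comparisons of chimeras with unmanipulated mice shared 53 called genes with the same sign, 13 higher and 40 lower, against 0.5 and 3.7 for independent lists, and 0 with opposite signs, against 2.8, all from limma. Jun and Egr1, lower in both, lost their call in WM IMP against WT IMP with the hybridization covariate, and Jun lost that in MW naive against WT naive with the Gapdh covariate. The median of the TCR immediate early list went from -0.42 to -0.54 in the first of these fits, where the median SE of called genes rose from 0.20 to 0.30. In the second it went from -0.55 to -0.34. Across all genes the log2 differences had Pearson's r = 0.435 and Spearman's rho = 0.424, and genes are not independent replicates. The shared count was 54 with the poly-A difference as a block and 0 in the 7 arrays without high poly-A controls, and it ranged from 2 without WT IMP 2 to 117 without WM IMP 2. It was 2 with the Gapdh, 11 with the actin and 1 with the hybridization covariate, and 0 in fits to 2 groups.

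Called genes were also counted by chromosome. With Fisher's exact test (two-sided) over 20 chromosomes, 0 passed after Benjamini-Hochberg adjustment in MW naive against WT naive or in WM IMP against WT IMP, and 1 in each had an unadjusted p under 0.05. With each probe set by itself 1 chromosome passed in each, and with genes called at an adjusted p under 0.01 1 passed in WM IMP against WT IMP. In the latter comparison the chromosome under 0.05 was chromosome 1, where 23 of 1067 genes were called, 2.20% against 1.20% elsewhere (Fisher's exact p = 0.00929, adjusted p = 0.186). Chromosome 17, which holds the MHC, had 34 of 828 genes called in MW naive against WT naive, 4.10% against 3.0% elsewhere (Fisher's exact p = 0.0610, adjusted p = 0.305).

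**Figure D3:**
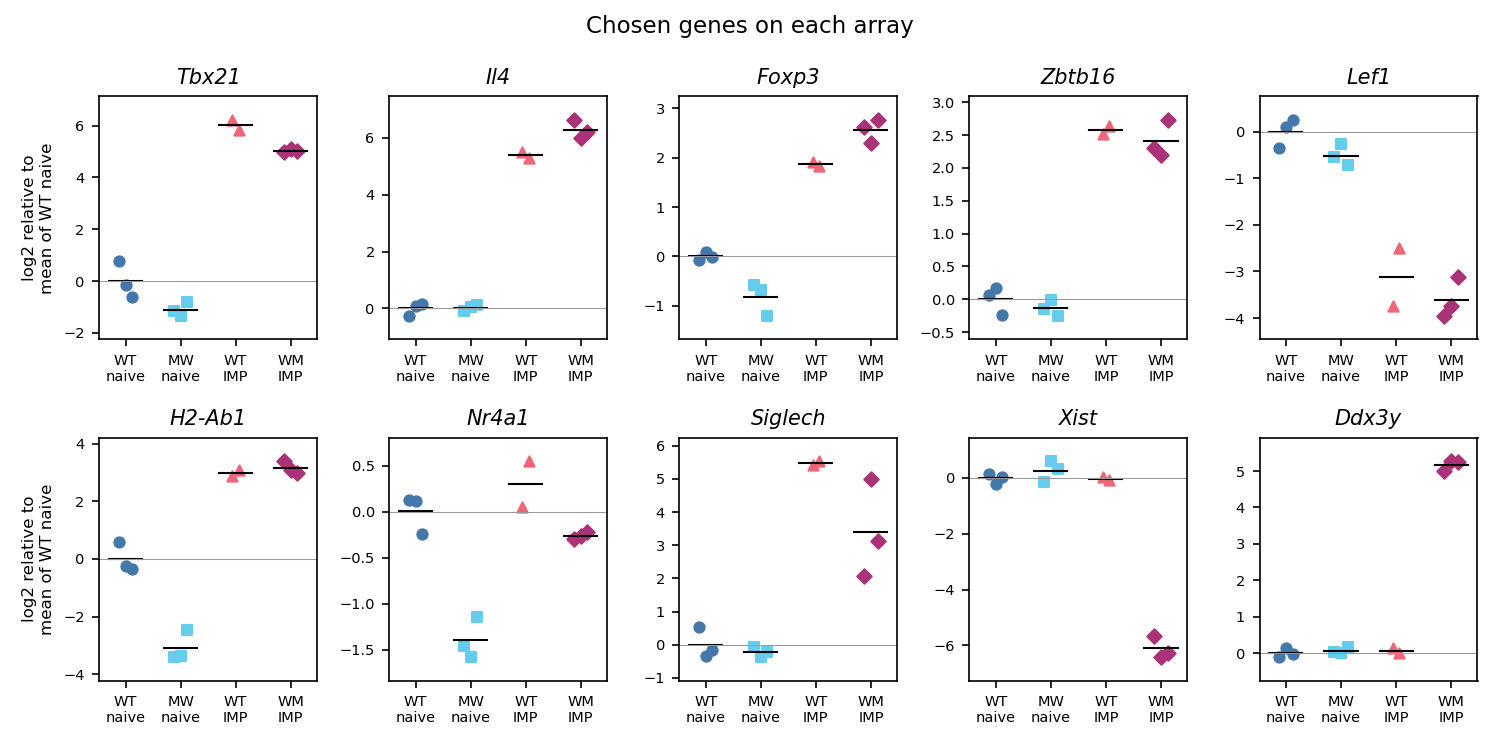
Log2 values relative to the mean of WT naive for 10 genes, with 1 point per array (3, 3, 2 and 3 arrays) and the group mean as a line. Tbx21, Il4 and Zbtb16 are high in both IMP groups, Nr4a1 is lower in MW naive than in WT naive, and Xist is at -5.65 or below in the 3 WM IMP arrays alone.

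**Figure D4:**
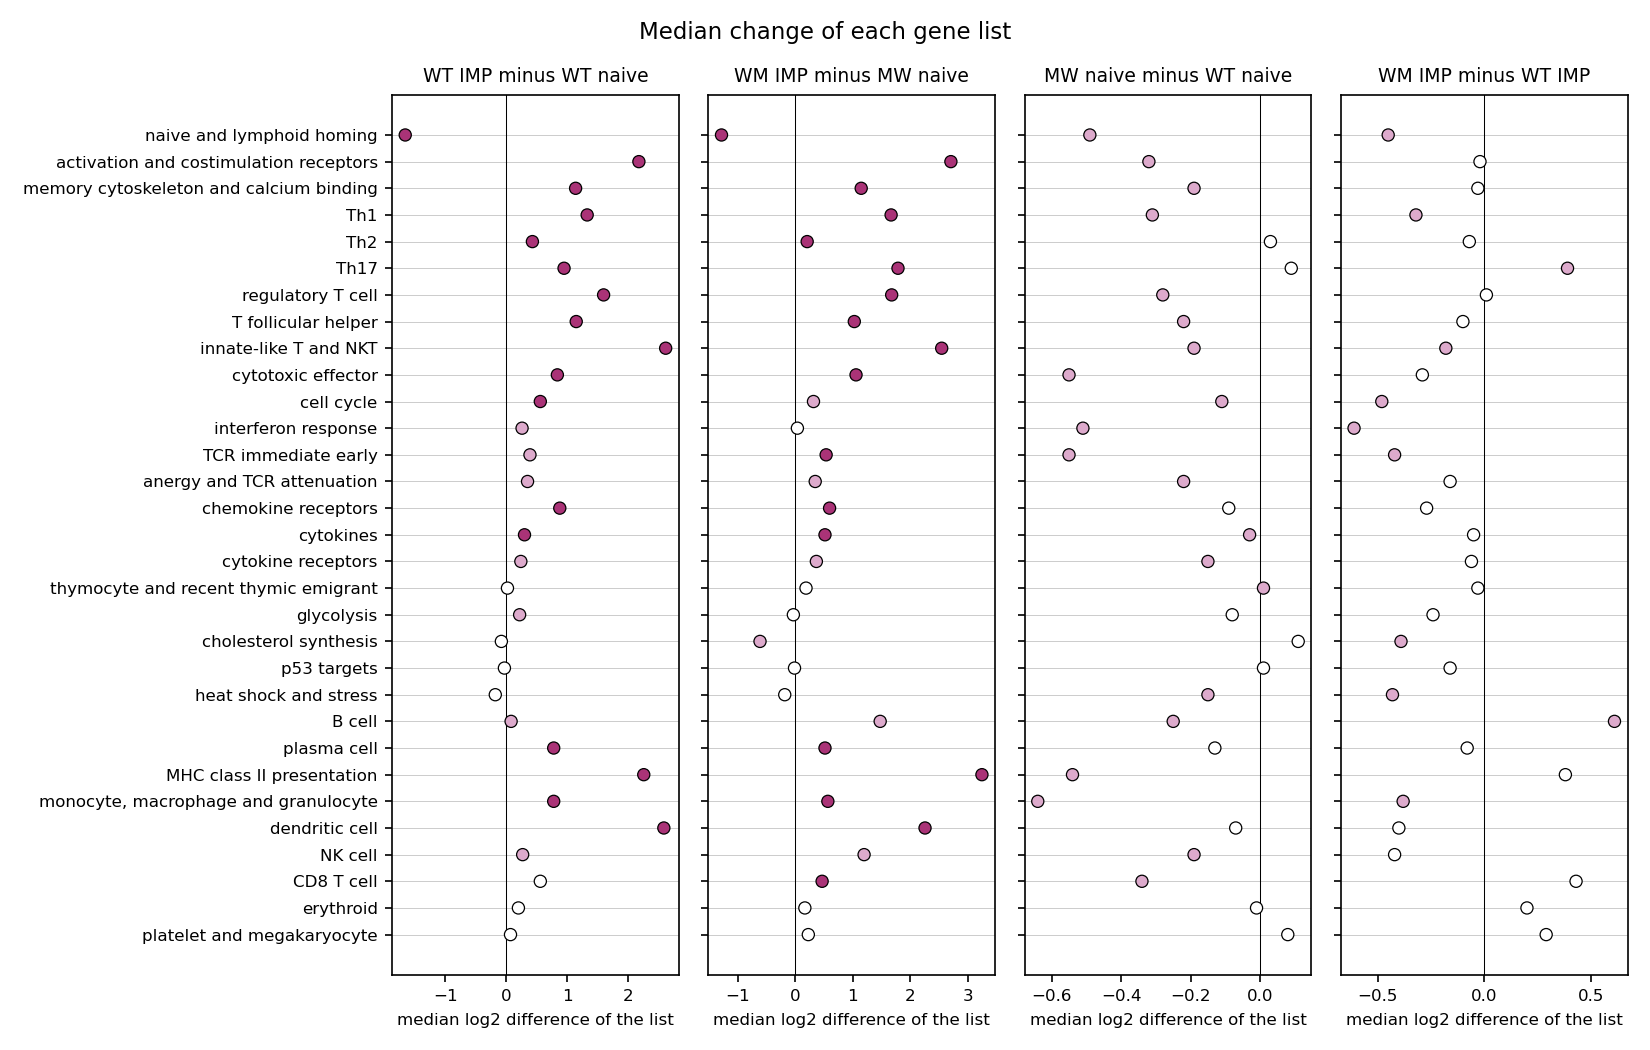
Median log2 difference of the measured members of each of the 31 gene lists in 4 comparisons. Dark points passed limma's camera at an adjusted p under 0.05 also with an estimated correlation, pale points passed with the preset correlation alone and open points did not pass, and the lists that passed in MW naive against WT naive are all pale.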

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

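Of the tests below, those of male cells, of a lower share of T cells and of donor DNA around the CD45 gene and around the MHC were chosen only after the result was seen, as were the fits with the hybridization, Gapdh or actin covariate.

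In the interaction, the difference between IMP and naive cells itself differed between chimeras and unmanipulated mice for 12 genes: Xist (-6.35), Ddx3y (5.05), Trnp1 (-3.67), H2-Ab1 (3.22), Eif2s3y (3.03), Ctse (2.80), Ifitm3 (2.79), G530011O06Rik (2.68), Ppfia4 (-2.47), Kdm5d (1.74), Igfbp4 (1.59) and Gprc5b (1.55), all in log2. Of these, H2-Ab1, Trnp1 and Ifitm3 differed from unmanipulated mice mainly in MW naive (-3.07, 3.85 and -2.21 relative to WT naive), whose marrow lacks MHC class II. Ctse and Ppfia4 lie among the 200 genes around Ptprc that are described below. Signals outside the main measurement also stood apart. Control probe sets for poly-A RNA were at least 3.86 in 1 array of each group, and those for hybridization averaged 1.85 higher in the chimera arrays than in those of unmanipulated mice.

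Xist was at -5.65, -6.42 and -6.27 in the 3 WM IMP arrays, and 4 of 11 tested Y-linked genes were called higher there (Ddx3y, Eif2s3y, Kdm5d and Uty, the last by 0.97 ± 0.12), although the labels give female donors and hosts. The hybridization level of the arrays was argued against, since 4 of 4 genes (Xist, Ddx3y, Eif2s3y, Kdm5d) kept their call with it as a covariate, with Xist at -6.56 ± 0.41 and Ddx3y at 5.19 ± 0.24. In each WM IMP array the 4 called Y-linked genes lay above every array of the other groups, by at least 0.75, and Xist lay at least 5.45 below. Female cells carry no Y chromosome and make Xist, which was 68.3-fold lower in WM IMP than in WT IMP. Both signs, seen in each of the 3 arrays, argue against female cells as the bulk of WM IMP, although the labels give them. Mostly male cells would give both signs, and where such cells came from was not tested. A test on X genes that escape inactivation did not decide by itself: 5 of 5 were lower in WM IMP, but their median of -0.15 was within their SD of 0.43 and 1 was called (Pbdc1, -1.01 ± 0.21). No test could separate donor sex from the group, and such a sex difference adds to the transplantation in every comparison of WM IMP.

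Dendritic cell markers were higher in IMP than in naive arrays although the sort gated on TCRβ and CD4. The sort purity of 92% to 99% leaves room for some other cells. Of 11 plasmacytoid markers not looked at before, 7 were called higher in WT IMP, among them Upb1 (4.76), Smim5 (4.25) and Cox6a2 (3.84), and between WM IMP replicates 2 and 1, with the most and the least Siglech, the called ones differed by a median of 1.82 (SD 1.67), against -0.07 (SD 0.79) for called Th1 genes. Of the 7, 5 were higher in replicate 2, while Tlr7 (-0.25) and Cybb (-0.74) were lower. Of 10 markers seen before, 7 were higher and Blnk (-1.35), Spib (-0.39) and Ccr9 (-0.30) lower. The difference of 1.89 between the medians, from 1 array against 1, is what dendritic cells carried over in the sort would give for part of these markers. The 9 called members of the dendritic cell list differed by a median of 0.86. Replicates 2 and 1 also differ in the controls for poly-A (6.11 against -1.99) and hybridization (2.38 against 3.85) and in the Gapdh 5' minus 3' difference (-2.71 against 0.56). The test does not separate these from carried-over cells. A lower share of T cells that raises every other type alike was set against 3 lists. In WT IMP 3 of 3 (B cells 0.08, red cells 0.20, platelets 0.07) had a median rise under 50% of that of the dendritic list (2.59), by more than the spread of the members. In WM IMP against MW naive 2 of 3 did (red cells 0.17 and platelets 0.23 against 2.26), but the B cell list rose by a median of 1.48 (SD 0.88), so B cells rising with the dendritic markers stay open there. Outside this test, the monocyte, macrophage and granulocyte (median 0.78), plasma cell (0.78) and NK cell (0.27) lists passed higher in WT IMP with camera. Signal over background is unknown and the red cell list was measured without the globin genes, so a flat list may have been unable to rise. The values argue against an equal rise of every type, but a lower share of T cells was not excluded. Expression of these genes by the T cells themselves stays open, and no biological explanation was tested.

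Genes that differ between chimeras and unmanipulated mice were set against RNA integrity, the hybridization level and donor DNA. Across the 556 genes called between MW naive and WT naive, which are not independent replicates, the difference of WT IMP replicate 1 from replicate 2 correlated with that contrast at r = 0.543, so RNA degradation may account for part of it. These 2 arrays also differ in the poly-A controls, so the r alone does not separate the 2 differences. Poly-A controls were high in 1 of 3 arrays of each naive group, so a block for them could not change the differences of this contrast. With that block 473 of the 556 genes kept their call, which decides nothing about the r. The same measure for the hybridization level gave r = -0.082 (WM IMP 1 against the other 2). WM IMP 1 also differs from these in the Gapdh 5' minus 3' difference (0.56 against -2.71 and -1.69). This r therefore does not separate the hybridization level from RNA integrity and decides nothing by itself. With that level as a covariate the median absolute difference of the 556 genes stayed at 0.89 and their median SE went from 0.17 to 0.22. Of them 216 kept their call. In the 340 that lost it the median difference went from 0.79 to 0.74 and the median SE from 0.16 to 0.21. The median over the 556 genes did not fall, which argues against the hybridization level as the whole cause. The covariate fit draws in part on the same WM IMP arrays, however, and a part in single genes stays open. With the Gapdh covariate the count was 14, the median absolute difference of the 556 genes went from 0.89 to 0.75 and their median SE from 0.17 to 0.21, so calls ended through both. In WM IMP against WT IMP 166 of 259 genes kept their call with that covariate, with the median absolute difference at 1.10 and the median SE at 0.20 in both fits, which argues against the Gapdh trend as the whole cause there. With the actin covariate 72 kept it, with the median difference at 1.10 and the median SE at 0.24, and with the hybridization covariate 6, at 0.90 and 0.30, so neither was excluded for the other genes. Among 200 genes around Ptprc, which encodes CD45, 11 were called in WM IMP against WT IMP, 5.50% against 1.20% elsewhere (Fisher's exact p = 4.05e-05, adjusted over 4 tests 0.000162), so donor DNA around that gene could explain some calls. Ctse (3.67) and Ppfia4 (-2.34) were among the 11 and had the greatest log2 differences of them. Of the 11, Btg2, Prg4 and Rnpep were called lower in MW naive against WT naive too. Without genes called in both, the count was 8 of 197, 4.10% against 0.9% (Fisher's exact p = 0.000743). In MW naive against WT naive 10 of the 200 were called, 5.0% against 3.0% (Fisher's exact p = 0.0965), and around H2-Ab1, with H2-Ab1, H2-Aa and H2-Eb1, all called lower, left out, 10 of 198, 5.10% against 3.0% (Fisher's exact p = 0.0917), which did not decide. Around H2-Ab1 1 of 198 was called in WM IMP against WT IMP, 0.5% against 1.20% (Fisher's exact p = 0.524). Effects of irradiation, of transplantation and of the lack of MHC class II were not tested and stay open.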

How the results depend on the processing

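Robust eBayes, the choice of probe set, the poly-A block, the 7 arrays, the covariates and the removal of X and Y genes were chosen after seeing the data. The number of arrays limits the precision, WT IMP has 2 arrays, and signal over background is unknown. Where no reason is given, the cause was not tested. A filter on dim genes, cyclic loess and an intensity trend could not be run without brightness. Of single named genes under all alternatives, 4722 tests gave the same call, 435 lost the call and 12 gained it. No direction reversed where the gene was called in either fit, and changes of sign in genes called in neither were not counted.

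The replicate numbers did not pair the samples: the 15 same-numbered pairs had a median r of -0.02 and 2 were over 0.1. With the replicate number as a block the counts were 299 for MW naive against WT naive, 101 for WM IMP against WT IMP, 7 for the interaction and 26 for the overlap of both chimera contrasts. The other counts moved less than 1.5-fold.

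In fits to 2 groups the counts were 1530 for WM IMP against MW naive, 929 for MW naive against WT naive, 8 for WM IMP against WT IMP and 0 for the overlap of both chimera contrasts in limma. With array weights they were 3052 for WT IMP against WT naive, 2048 and 453 for the naive and IMP contrasts of chimeras, 58 for the interaction and 182 for the overlap of chimera contrasts. With each probe set by itself they were 4139 for WM IMP against MW naive, 1255 and 941 for the naive and IMP contrasts of chimeras, 5628 for the average and 28 for the interaction. The other deposited table gave 24 for the interaction and 82 for the overlap of chimera contrasts. The probe set with the highest relative mean gave 337 for MW naive against WT naive, and that with the widest range gave 841, with 510 for WM IMP against WT IMP and 128 for the overlap.

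At an adjusted p under 0.01 the counts were 821, 1414, 108, 31, 2102 and 6 for WT IMP against WT naive, WM IMP against MW naive, MW naive against WT naive, WM IMP against WT IMP, the average and the interaction, and the overlaps were 626 and 2. With a change of at least 2-fold as well they were 937, 1151, 231, 160 and 996 for the first 5, and the overlaps 644 and 22. Both counts fall by construction.

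In the 7 arrays without high poly-A controls, which leave fewer arrays, the 6 counts were 478, 1160, 15, 9, 1539 and 1, and the overlaps 377 and 0. The poly-A block gave 1504, 2698, 543, 196, 3567 and 18, and the overlaps 1093 and 54. The hybridization covariate gave 1667 for WM IMP against MW naive, 7 for WM IMP against WT IMP and 1 for the overlap of chimera contrasts, and 10 and 5 lists passed for the naive and IMP contrasts of chimeras. The Gapdh covariate gave 1020 for WT IMP against WT naive, 14 for MW naive against WT naive, 4 for the interaction and 2 for the overlap of chimera contrasts. The actin covariate gave 88 and 131 for the naive and IMP contrasts of chimeras and 11 for their overlap. Without X and Y genes the interaction had 2.

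Camera with an estimated correlation passed 0 lists for MW naive against WT naive, for WM IMP against WT IMP and for the interaction, and fry passed 12 for MW naive against WT naive and 0 for the interaction. Of chromosomes, 1 passed for each chimera contrast with each probe set by itself, and 1 for WM IMP against WT IMP at an adjusted p under 0.01.

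With each array left out in turn the counts ranged from 702 (without WT IMP 1) to 2067 for WT IMP against WT naive, from 1812 to 2879 for WM IMP against MW naive, from 123 (without MW naive 2) to 1017 (without WM IMP 1) for MW naive against WT naive, from 14 (without WT IMP 2) to 929 (without WM IMP 2) for WM IMP against WT IMP, from 2309 to 4063 for the average and from 4 to 63 for the interaction. The overlaps ranged from 604 to 1426 and from 2 to 117. Lists passing ranged from 21 to 24, 24 to 25, 17 to 20, 10 to 14, 23 to 25 and 8 to 14. Where WT IMP kept 1 array, its spread was assumed to be that of the other groups.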

Other observations

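The tests in this part were planned before their result was seen.

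Other splits of the same arrays were fitted in place of the real groups. For MW naive against WT naive, 929 genes were called by limma in the real split and at most 0 in the other 9 of 10, and 19 lists passed against at most 15. For WM IMP against MW naive the real split gave 1530 genes against at most 0, and 24 lists against at most 19. In each of these 4 results 1 of the 10 splits, the real one, gave as many, and 10 splits are too few for a share under 0.05. For all 5 IMP against all 6 naive arrays, 2802 genes were called against at most 733 in the other splits drawn. There 1 of 100 splits, the real one, gave as many, a share under 0.05, which argues against chance for the gene count. Chance was not excluded, since the arrays come from 4 groups and are not interchangeable. For the number of lists, 23 in the real split, 12 of 100 splits gave as many and the highest gave 25, so chance was not excluded.

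The spread of an array around its group mean differed between arrays. Outside WT IMP the residual SD ranged from 0.145 in WT naive 1 to 0.347 in WM IMP 1. Both WT IMP arrays were at 0.138. With 2 arrays in a group these values are equal by construction and shrunk more than in the larger groups. They therefore do not rank WT IMP against the other groups.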
